A study of Homo sapiens with 9 samples.

How the data were processed

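Poly(A) mRNA of 9 U2OS libraries, 3 each from WT, clone1 and clone2, was sequenced on a DNBSEQ platform. The deposited table holds 18119 genes with 48 value columns. Estimated counts (expected counts) and TPM are the units of the 18 columns used, per the file headers, with 1 column of each kind per library. The other 30 value columns were not used. The genome was hg38 per the submitters' processing notes; the aligner, the counting tool, the annotation and their versions are not given in the sources used here. Between 14.8% and 16.0% of the deposited count values in a library were not whole numbers, and the expected counts were rounded to whole numbers before testing. Library totals were 14915958, 14944180 and 15133239 counts in WT, 15856915, 16058560 and 15624125 in clone1, and 16411147, 15766295 and 16126011 in clone2.

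Genes with enough counts by filterByExpr in edgeR 4.0.16 (14098 genes) were scaled by TMM and fitted with a quasi-likelihood model with 1 mean per group, which left 6 residual degrees of freedom. The clones were each compared with WT and clone2 was compared with clone1. P-values were adjusted by the method of Benjamini and Hochberg over the genes tested, and a gene passed at an adjusted p under 0.05. CPM are counts scaled by TMM to 1000000 per library. The SE of a log2 fold change is its absolute value divided by the square root of the quasi-likelihood F statistic. For large changes to or from few counts this SE is smaller than the counting error and understates the uncertainty. Genes that passed in both clones with the same sign were counted as shared, and this count was set beside independent lists and beside 50 simulated sets in which neither clone differed from shared WT libraries. Folds against a group without counts were computed against a floor of 3 counts over the group, and genes with 1 to 3 counts in a group were given with a 95% counting interval. Floors and intervals cover counting error only.

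Of 38 gene lists written by hand, with 608 of 638 entries found in the table, 34 had at least 5 tested genes. They were tested with camera in limma 3.58.1 at a preset correlation of 0.01 on log2 CPM with a prior count of 2, and p-values were adjusted over the lists of a comparison. Camera compares the genes of a list with all other genes. The alternative test, fry, asks whether the genes of a list move on balance to 1 side and does not compare them with other genes. Members were also counted with p-values adjusted over the list alone.

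The genes named were chosen by rule: CIART; for each clone against WT, the 10 largest rises and the 10 largest falls among genes that passed, with a mean of at least 5 CPM in the clone or WT, no overlap between the libraries and a gene symbol; the 8 largest in each direction in both clones by the smaller absolute change; the 6 largest in each direction between the clones; every tested member of the E-box and ROR-element clock lists; and up to 4 members of every other list with the smallest adjusted p. This gave 281 genes. A few of them are not reported here. Gene positions came from RefSeq annotation of GRCh38, which placed 99.6% of the genes. Running medians covered 41 neighbouring genes at 5 CPM or more. Runs were sought with every other gene and measured on the genes held out.

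The comparisons, gene lists, naming rule and alternatives were set before the data were examined, except the removal of the running median of neighbouring genes, which was added later. The alternatives were DESeq2 size factors, no filter on low counts, a filter at a mean of 1 CPM, a term for the replicate number, leaving out each library, fits of only the groups compared, the Wald test of DESeq2 1.42.0, limma-trend on log2 TPM with 1 or 0.1 added, an adjusted p under 0.01, a change of at least 2-fold, and for lists an estimated correlation and fry. The other software was R 4.3.3, Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.

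The model was tested on simulated data for clone1 against WT with 50 changed genes per fold. It called 39 of 50 genes changed 1.25-fold, 49 at 1.5-fold, 49 at 2-fold and 50 at 4-fold, with 9 false calls among 13957 genes tested. A simulated unchanged clone2 gave 0 calls, and camera recovered the shifted list with 0 others called. This simulation does not measure how often camera calls lists falsely in the real libraries. There, splits that mixed the libraries of clone1 and WT still passed up to 7 lists. Splits that mixed clone2 with WT, or clone2 with clone1, passed up to 11. Such splits keep part of the difference between the groups, so these numbers are not counts of false calls. A simulated run of neighbouring genes shifted by -0.5 was measured at -0.50. Correlations of log2 CPM between libraries, checked for duplicates, were 0.993 to 0.995 within groups and 0.968 to 0.989 between groups, and 0 libraries were duplicates.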

Results

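Poly(A) RNA was sequenced from 9 libraries of U2OS, a human osteosarcoma cell line. The labels give 3 libraries of wild-type cells (WT), 3 of a first clone (clone1) and 3 of a second (clone2). Both clones are called CHRONO overexpressed in the sample labels, whereas the design text of the series speaks of a CHRONO knockout. CHRONO is the product of CIART, a repressor of the circadian activator formed by CLOCK and BMAL1. Library totals were 14915958 to 15133239 estimated counts in WT, 15624125 to 16058560 in clone1 and 15766295 to 16411147 in clone2. Of 18119 genes in the table, 14098 had enough counts to be tested. The comparisons ask how expression in each clone differed from WT, what both clones shared, and how the clones differed from each other. The labels do not say whether the libraries of a group came from separate cultures, so the p-values measure only the spread between these libraries, which can be technical (biological coefficient of variation 3.64%). They mention no empty-vector clone, so a difference between a clone and WT is not separated from the effect of picking a clone.

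CIART, on chromosome 1 from 150282554 to 150287093 in GRCh38, was far higher in every clone library than in WT. WT held 11.6 ± 0.37 CPM (mean ± SD, n = 3), clone1 5216 ± 88.4 and clone2 4083 ± 106.3, which is 449.6-fold and 351.9-fold the WT mean. The WT libraries lay between 11.4 and 12.03 CPM, those of clone1 at 5114, 5276 and 5257, and those of clone2 at 3960, 4140 and 4148. The log2 fold change was 8.81 ± 0.07 in clone1 (SE, adjusted p = 1.05e-37) and 8.46 ± 0.07 in clone2 (adjusted p = 2.77e-37). CIART took 0.519% to 0.534% of all counts in clone1 and 0.396% to 0.412% in clone2. Clone2 held less CIART than clone1, by a log2 fold change of -0.35 ± 0.04 (adjusted p = 1.1e-07). These levels go with the sample labels and against the design text. Counts per gene do not separate transcripts of the native gene from those of an introduced copy.

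Among clock genes, NR1D1 fell and BMAL1 rose in both clones. NR1D1 encodes REV-ERBα, a nuclear receptor that represses BMAL1 transcription, and lies on chromosome 17 from 40092793 to 40100589. Its mean fell from 43.3 CPM in WT to 8.37 in clone1 and 11.6 in clone2 (log2 fold change -2.37 ± 0.08 and -1.90 ± 0.07, SE, n = 3 per group, as for all values below). BMAL1, listed as ARNTL and located on chromosome 11 from 13276652 to 13387266, rose from 33.2 CPM to 69.7 and 74.8 (1.07 ± 0.05 and 1.17 ± 0.05). The period gene PER2 rose (0.84 ± 0.09 and 0.61 ± 0.09), PER3 fell (-0.56 ± 0.06 and -0.27 ± 0.06), and the cryptochromes CRY1 (0.35 ± 0.06 and 0.36 ± 0.06) and CRY2 (0.64 ± 0.07 and 0.51 ± 0.07) rose in both clones. The sample titles give no time of harvest and no synchronisation of the cultures. A change in the level of a clock gene is therefore not separated from a change in its timing.

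**Figure D1:**
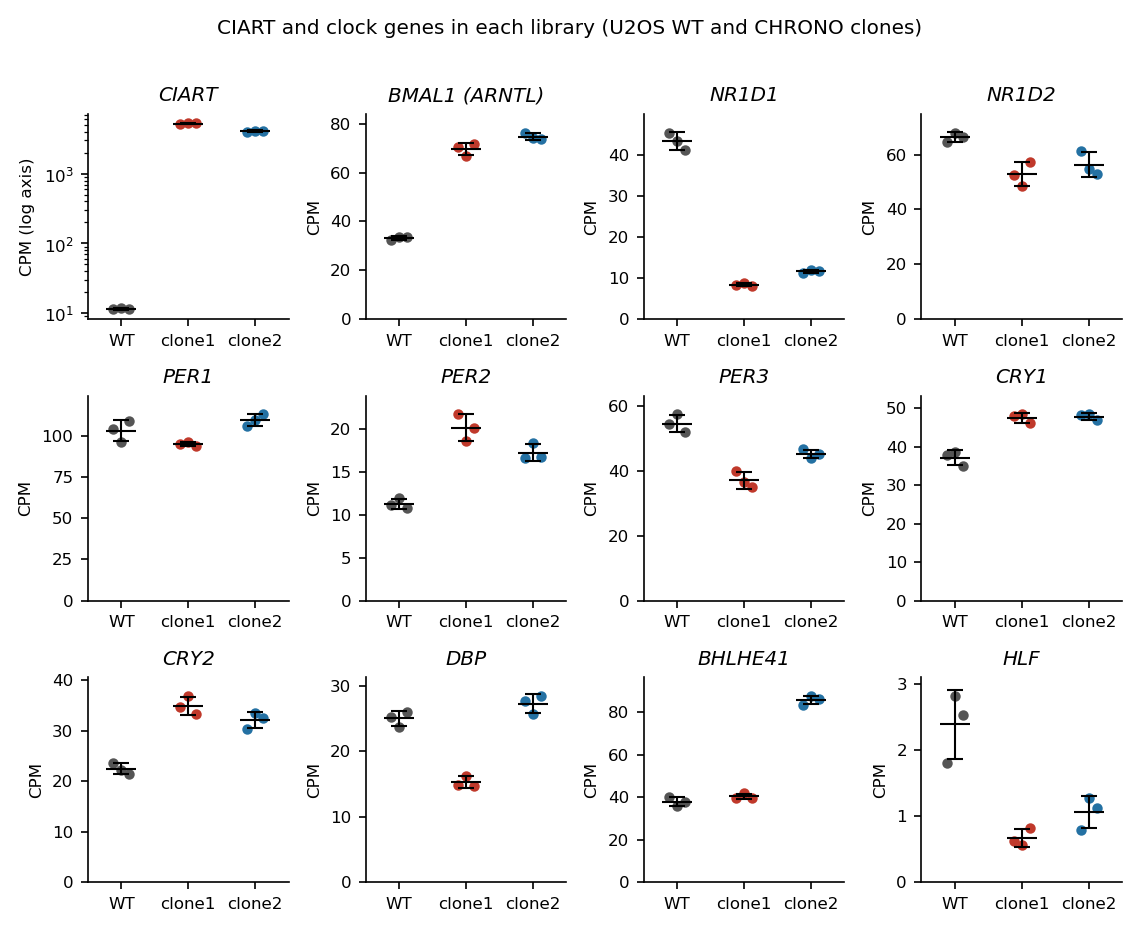
Expression of CIART and clock genes in each library, in CPM, by group (WT, clone1, clone2; 3 libraries each, mean and SD drawn over the points). CIART lay near 11.6 CPM in WT and at 5216 and 4083 CPM in the clones, while NR1D1 fell from 43.3 to 8.37 and 11.6 CPM.

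Other members of the 12-gene list of E-box clock output, genes driven through the promoter element that CLOCK and BMAL1 bind, moved in both directions. HLF (-1.83 ± 0.28 and -1.17 ± 0.25, at 2.39 CPM in WT), NR1D2 (-0.33 ± 0.06 and -0.24 ± 0.06) and BHLHE40 (-0.27 ± 0.05 and -0.43 ± 0.05) fell in both clones. DBP fell in clone1 (-0.71 ± 0.08), where BHLHE41 did not pass (0.09 ± 0.06), while in clone2 BHLHE41 rose (1.18 ± 0.05) and DBP did not pass (0.12 ± 0.07). PER1 (-0.12 ± 0.05) and TEF (-0.18 ± 0.07) fell in clone1 alone among the comparisons with WT, and did not pass in clone2 (0.09 ± 0.05 and 0.02 ± 0.07). In clone1, 3 members rose and 8 fell (3 and 8 adjusted over the list alone), and the list as a whole did not pass camera (adjusted p = 0.202) but passed fry (adjusted p = 9.48e-06, down). In clone2, 4 rose and 5 fell (4 and 5 adjusted over the list alone), and the list did not pass camera (adjusted p = 0.742; its median was 0.05 and its test up, its mean -0.09). In the 6-gene list of clock genes driven through ROR elements, ARNTL, NPAS2 (0.44 ± 0.05 and 0.18 ± 0.05) and RORA (0.54 ± 0.07 and 0.26 ± 0.08) rose, while CLOCK (-0.17 ± 0.06 and -0.32 ± 0.06) fell. NFIL3 did not pass in clone1 (0.04 ± 0.07) or clone2 (0.15 ± 0.06). This list did not pass camera in clone1 (3 rose and 2 fell, 3 and 2 adjusted over the list alone, adjusted p = 0.21) or in clone2 (3 and 2, 4 and 2 adjusted over the list alone, adjusted p = 0.379), and passed fry in both (adjusted p = 1.57e-06 and 9.74e-07, up).

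Several of the small clock-gene calls ended or changed sign under other settings. The clone1 call of PER1 ended without WT replicate 1 or 3 or clone1 replicate 1 or 3 (-0.12 to -0.08). That of TEF ended without WT replicate 1 or 2 or clone1 replicate 1 (-0.17 to -0.15). That of CLOCK ended without WT replicate 2 or clone1 replicate 2 or 3 (-0.14 to -0.11). The NPAS2 call in clone2 ended without clone2 replicate 2 (0.14). With the running median of neighbouring genes removed, TEF in clone1 (0.13), CLOCK in clone1 (0.10) and clone2 (0.02) and RORA in clone2 (-0.04) changed sign and none of them passed, the PER1 call in clone1 ended (-0.06) and TEF passed in clone2 (0.21). With DESeq2 the clone1 calls of PER1 (-0.12) and TEF (-0.18) ended. With TPM in place of counts, the calls of PER1 (-0.04), TEF (-0.08) and CLOCK (-0.06) in clone1 and of PER3 (-0.18) and NR1D2 (-0.18) in clone2 ended. With TPM BHLHE41 passed in clone1 (0.17) and PER1 (0.13) and NFIL3 (0.19) in clone2.

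Against WT, C6orf15, MMP9 and LAMA3 rose in clone1, and DHRS2, OLR1 and VCX were nearly lost. C6orf15 rose from 3.31 ± 0.569 to 34.2 ± 3.095 CPM (SD, log2 fold change 3.37 ± 0.11), MMP9, a secreted gelatinase, from 2.19 ± 0.436 to 16.8 ± 1.70 CPM (2.94 ± 0.14), and LAMA3, a laminin chain, from 1.74 ± 0.352 to 10.8 ± 1.51 CPM (2.63 ± 0.16). DHRS2, a short-chain dehydrogenase, fell from 425.2 ± 18.8 to 1.56 ± 0.275 CPM (-8.08 ± 0.08), and OLR1, a receptor for oxidised lipoprotein, from 31.5 ± 1.39 to 0.188 ± 0.126 CPM (-7.33 ± 0.19). For these and other large falls to few counts the SE is too small. VCX3A and SPATA31C2 had no counts in clone1, which puts them at least 108.6-fold and 91.8-fold lower than WT. VCX fell 621.3-fold (95% counting interval 111.1 to 24583).

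Besides CIART, the 10 genes that rose most in clone1 by the naming rule also included the protocadherin PCDHB6 (2.69 ± 0.11), the potassium channel KCNH1 (2.63 ± 0.16), the hyaluronan link protein HAPLN2 (2.58 ± 0.16), C5orf46 (2.42 ± 0.13), the chemokine CCL24 (2.36 ± 0.12), the contactin CNTN1 (2.31 ± 0.12) and LCTL (2.05 ± 0.09), which lies in a run of neighbouring genes on chromosome 15 that were higher in both clones. The 10 that fell most included the transcription factor ETV1 (206.2-fold lower, 95% counting interval 56.7 to 1709), the cancer-testis gene PAGE1 (-7.34 ± 0.20), PNMA5 (-6.76 ± 0.25), the melanosome transport gene MLPH (120.3-fold lower, 40.8 to 586.5) and PAGE5 (lower by a fold within a 95% counting interval of 27.0 to 390.8). VCX, VCX3A, PAGE5 and SPATA31C2 share most or part of their sequence with related genes, so which copy their reads came from is uncertain. In all, 6893 genes passed in clone1, 3400 higher and 3493 lower. With TPM in place of counts (1 added), which moved the median of all genes by 0.08, the split was 4538 higher and 2360 lower. Of the 6893 genes called from counts, 76.2% differed by less than 1.5-fold, and 669 passed with at least 2-fold, 168 higher and 501 lower. The clone1 and WT libraries did not overlap for 55.3% of the genes tested, where chance gives 10%.

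Lists of protein synthesis and of lipid and amino acid metabolism were called down in clone1. Of 32 cytosolic ribosomal protein genes, 30 fell (32 adjusted over the list alone) and none rose, with a median of -0.39 (adjusted p = 3.97e-11; adjusted p = 0.291 with an estimated correlation). RPL30 fell by 0.54 and RPS3 by 0.52 on the log2 scale. Of 19 cholesterol synthesis genes, 17 fell (17 adjusted over the list alone), among them the squalene synthase FDFT1 (-0.78 ± 0.05) and HMGCS1 (-0.67 ± 0.05), with a median of -0.38 (adjusted p = 2.55e-07; adjusted p = 0.104 with an estimated correlation). Of 19 genes of the ATF4 amino acid response, 18 fell (18 adjusted over the list alone), among them TRIB3 (-0.95 ± 0.06) and ATF4 itself (-0.57 ± 0.04), with a median of -0.42 (adjusted p = 3.14e-07; adjusted p = 0.116 with an estimated correlation). Fatty acid synthesis fell in 9 of 12 genes (9 adjusted over the list alone), including FASN (-0.45 ± 0.04) and ACSS2 (-0.80 ± 0.07), with a median of -0.36 (adjusted p = 6.55e-04; adjusted p = 0.122 with an estimated correlation). In the unfolded protein response list 10 of 16 genes fell (10 adjusted over the list alone), including HYOU1 (-0.37 ± 0.04), with a median of -0.16 (adjusted p = 2.08e-03; adjusted p = 0.28 with an estimated correlation). Of 17 NRF2 targets 10 fell and 1 rose (10 and 1 adjusted over the list alone), including TXNRD1 (-0.65 ± 0.04), with a median of -0.20 (adjusted p = 0.0338; adjusted p = 0.156 with an estimated correlation).

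Matrix, adhesion, skeletal and interferon-stimulated lists were called up in clone1. Of 22 collagen and matrix genes 16 rose and 3 fell (17 and 3 adjusted over the list alone), including thrombospondin THBS1 (1.48 ± 0.04), COL6A3 (1.11 ± 0.05) and fibronectin FN1 (1.18 ± 0.05). The list tested as up with a median of 0.37 (adjusted p = 8.59e-05; adjusted p = 0.291 with an estimated correlation), while its mean was -0.03. Of 17 adhesion and integrin genes 13 rose and 3 fell (13 and 3 adjusted over the list alone), including L1CAM (1.23 ± 0.06) and ITGB3 (1.82 ± 0.09), with a median of 0.32 (adjusted p = 2.08e-03; adjusted p = 0.291 with an estimated correlation). Osteoblast markers rose in 6 of 9 genes and fell in 1 (6 and 1 adjusted over the list alone), including RUNX2 (0.65 ± 0.06) and ALPL (0.78 ± 0.13), with a median of 0.27 (adjusted p = 8.95e-03; adjusted p = 0.116 with an estimated correlation). The call of this list ended without the filter on low counts. Chondrocyte markers rose in 5 of 7 genes (5 adjusted over the list alone), including SOX9 (0.65 ± 0.05) and ACAN (0.86 ± 0.07), with a median of 0.42 (adjusted p = 0.0153; adjusted p = 0.201 with an estimated correlation). Of 22 interferon-stimulated genes 15 rose and 3 fell (15 and 4 adjusted over the list alone), including RSAD2 (1.00 ± 0.06) and IFIH1 (0.95 ± 0.06), with a median of 0.32 (adjusted p = 2.08e-03; adjusted p = 0.116 with an estimated correlation). BST2 fell (-3.25 ± 0.19).

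The NF-kB inflammatory and p53 lists were called down in clone1. Of 17 NF-kB inflammatory genes 11 fell and 2 rose (12 and 2 adjusted over the list alone), including TNFAIP2 (-5.04 ± 0.13), the adhesion receptor ICAM1 (-3.50 ± 0.16) and the chemokine CXCL8 (-1.47 ± 0.09), with a median of -0.42 (adjusted p = 3.11e-03; adjusted p = 0.116 with an estimated correlation). Of 22 p53 targets 10 fell and 1 rose (10 and 1 adjusted over the list alone), including the stress cytokine GDF15 (-1.59 ± 0.08) and FDXR (-0.50 ± 0.05), with a median of -0.10 (adjusted p = 0.0137; adjusted p = 0.116 with an estimated correlation). Of 24 G2/M genes 13 rose and 3 fell (15 and 3 adjusted over the list alone), including CCNB2 (0.38 ± 0.04) and DLGAP5 (0.46 ± 0.04), with a median of 0.10 (adjusted p = 0.0355; adjusted p = 0.345 with an estimated correlation). The G2/M call ended without WT replicate 1 (0.10) or clone1 replicate 2 (0.10), with a filter at 1 CPM (0.10) and with the median of neighbouring genes removed (0.10). In all, 14 of 34 lists passed in clone1 by camera at its preset correlation, 6 up and 8 down. With an estimated correlation 0 passed, with 8 at an unadjusted p under 0.05, and fry passed 26.

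Against WT, FNDC1, LEFTY1 and KCND3 rose in clone2, and DHRS2 and RAC2 were nearly lost. FNDC1, a fibronectin-domain protein, rose from 0.38 ± 0.038 to 12.4 ± 1.20 CPM (SD, log2 fold change 5.00 ± 0.21), LEFTY1, an antagonist of NODAL signalling, from 0.402 ± 0.066 to 7.74 ± 0.922 CPM (4.24 ± 0.22), and the potassium channel KCND3 from 2.79 ± 0.491 to 22.7 ± 0.764 CPM (3.02 ± 0.12). DHRS2 fell from 425.2 to 0.856 ± 0.277 CPM (-8.95 ± 0.09), and RAC2 from 110.7 ± 3.80 to 0.854 ± 0.197 CPM (-7.01 ± 0.10). The SE is too small for these falls to few counts and for the rises of FNDC1 and LEFTY1 from few counts. GAGE12E and GAGE12C, VCX, VCX3A, SPATA31C2 and PAGE5 had no counts in clone2, which puts them at least 342.3-fold, 207.9-fold, 109.0-fold, 92.1-fold and 80.3-fold lower than WT. The GAGE12 copies have the same counts, and their reads cannot be assigned to a copy, while the clone1 libraries spread widely (SD 3.55 CPM).

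Besides CIART, the 10 genes that rose most in clone2 by this rule also included C6orf15 (2.92 ± 0.11), the serotonin receptor HTR2A (2.90 ± 0.15), LAMA3 (2.88 ± 0.15), PCDHB6 (2.70 ± 0.11), MMP9 (2.60 ± 0.14), the chemokine CXCL14 (2.42 ± 0.18) and NWD1 (2.33 ± 0.22). PAGE1 (-7.52 ± 0.21) and MLPH (181.2-fold lower, 95% counting interval 49.8 to 1502) were again among the 10 that fell most. In all, 7193 genes passed in clone2, 3449 higher and 3744 lower. With TPM, which moved the median by 0.04, the balance turned to 3824 higher and 2891 lower. Of the 7193 genes called from counts, 74.7% differed by less than 1.5-fold, and 759 passed with at least 2-fold, 161 higher and 598 lower. The clone2 and WT libraries did not overlap for 57.3% of the genes tested, where chance gives 10%.

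Inflammatory genes, p53 targets and cholesterol synthesis fell in clone2 in calls that were kept with an estimated correlation. Of 17 NF-kB inflammatory genes 14 fell and 1 rose (14 and 1 adjusted over the list alone), with a median of -0.83 (adjusted p = 2.60e-06; adjusted p = 0.0265 with an estimated correlation). TNFAIP2 fell by 5.64, ICAM1 by 4.72 and CXCL8 by 2.57 on the log2 scale. Of 22 p53 targets 20 fell and 1 rose (21 and 1 adjusted over the list alone), including GDF15 (-2.38 ± 0.09) and the p53 inhibitor MDM2 (-0.54 ± 0.04), with a median of -0.32 (adjusted p = 2.60e-06; adjusted p = 0.0265 with an estimated correlation). Of 19 cholesterol synthesis genes 18 fell (18 adjusted over the list alone), including FDFT1 (-0.97 ± 0.05) and squalene epoxidase SQLE (-0.71 ± 0.04), with a median of -0.35 (adjusted p = 5.95e-07; adjusted p = 0.0354 with an estimated correlation).

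The interferon-stimulated list, called up in clone1, was called down in clone2. Of 22 such genes 14 fell and 1 rose (14 and 1 adjusted over the list alone), including the ubiquitin-like ISG15 (-0.70 ± 0.05), with a median of -0.33 (adjusted p = 5.60e-04; adjusted p = 0.0815 with an estimated correlation). Targets of YAP and TEAD fell in 9 of 14 genes (9 adjusted over the list alone), including CCN1 (-0.87 ± 0.05) and GADD45A (-0.97 ± 0.05), with a median of -0.49 (adjusted p = 1.91e-04; adjusted p = 0.15 with an estimated correlation). MAPK early and feedback genes fell in 11 of 18 and rose in 2 (11 and 2 adjusted over the list alone), including FOSL1 (-1.42 ± 0.07) and MYC (-0.55 ± 0.05), with a median of -0.20 (adjusted p = 0.0221; adjusted p = 0.463 with an estimated correlation). Ribosomal protein genes fell in 28 of 32 (28 adjusted over the list alone; median -0.28, adjusted p = 1.05e-06; adjusted p = 0.463 with an estimated correlation). The ATF4 list fell in 12 of 19 genes and rose in 1 (12 and 1 adjusted over the list alone), including TRIB3 (-1.31 ± 0.06), with a median of -0.18 (adjusted p = 2.55e-03; adjusted p = 0.386 with an estimated correlation). Fatty acid synthesis fell in 8 of 12 genes and rose in 2 (9 and 2 adjusted over the list alone; median -0.39, adjusted p = 3.11e-03; adjusted p = 0.203 with an estimated correlation).

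The cell-cycle lists were called up in clone2. Of 24 G2/M genes 20 rose and 1 fell (20 and 1 adjusted over the list alone), including CCNB2 (0.63 ± 0.04) and NUSAP1 (0.41 ± 0.04), with a median of 0.29 (adjusted p = 2.60e-06; adjusted p = 0.12 with an estimated correlation). Of 24 S-phase genes 17 rose and 2 fell (17 and 2 adjusted over the list alone), including cyclin E CCNE1 (0.56 ± 0.04) and E2F1 (0.36 ± 0.05), with a median of 0.23 (adjusted p = 9.27e-04; adjusted p = 0.43 with an estimated correlation). Thymidylate synthase TYMS fell (-1.74 ± 0.04). Chondrocyte markers rose in 6 of 7 genes (6 adjusted over the list alone), including HAPLN1 (1.00 ± 0.04), with a median of 0.41 (adjusted p = 9.87e-04; adjusted p = 0.12 with an estimated correlation). Collagen and matrix genes rose in 13 of 22 and fell in 4 (14 and 5 adjusted over the list alone), including SPARC (0.81 ± 0.04), with a median of 0.28 (adjusted p = 2.62e-03; adjusted p = 0.463 with an estimated correlation). Oxidative phosphorylation rose in 13 of 29 genes and fell in 2 (13 and 2 adjusted over the list alone), including SDHB (0.39 ± 0.04), with a median of 0.09 (adjusted p = 0.0269; adjusted p = 0.632 with an estimated correlation). Heat shock genes rose in 7 of 13 and fell in 1 (8 and 1 adjusted over the list alone), including HSPB1 (0.45 ± 0.05), with a median of 0.12 (adjusted p = 0.049; adjusted p = 0.466 with an estimated correlation). The oxidative phosphorylation call ended without WT replicate 2 (0.08) and the heat shock call without WT replicate 1 (0.13) or 3 (0.13) or clone2 replicate 2 (0.11) or with a filter at 1 CPM (0.11), and both ended with the median of neighbouring genes removed. In all, 15 of 34 lists passed in clone2 by camera, 6 up and 9 down. With an estimated correlation 3 passed, and by fry 29.

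**Figure D2:**
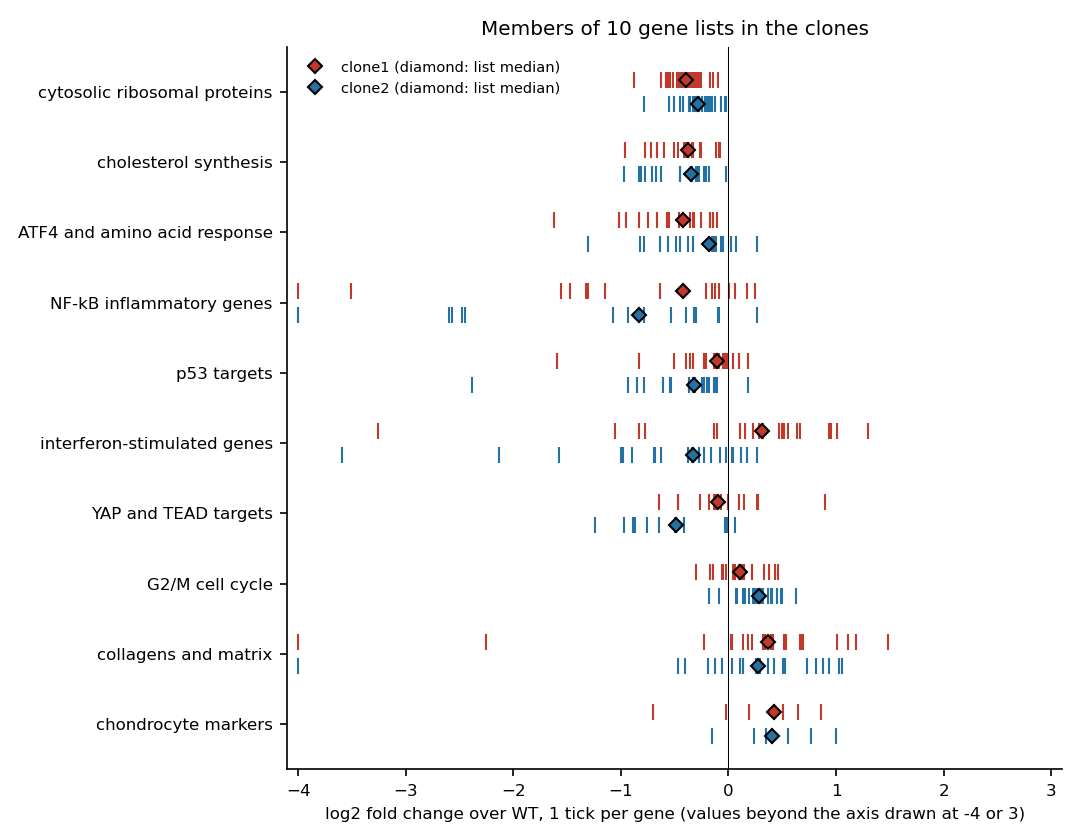
Log2 fold change over WT of the members of 10 gene lists in clone1 and clone2, with 1 tick per gene and diamonds at the list medians. The interferon-stimulated list lay at 0.32 in clone1 and -0.33 in clone2, and the NF-kB inflammatory list at -0.42 and -0.83.

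Both clones shared the rise of C6orf15, PCDHB6, LAMA3, MMP9, CCL24, C5orf46, KCNH1 and the protocadherin PCDHA1, and the near loss of VCX3A, SPATA31C2, VCX, DHRS2, PAGE1, PNMA5, MLPH and ETV1. In clone1 and clone2 CCL24 rose by 2.36 ± 0.12 and 2.23 ± 0.12 on the log2 scale, C5orf46 by 2.42 ± 0.13 and 2.18 ± 0.13, KCNH1 by 2.63 ± 0.16 and 1.98 ± 0.18, and PCDHA1 by 2.01 ± 0.13 and 1.92 ± 0.13. PNMA5 changed by -6.76 ± 0.25 in each clone, with an SE that is too small at so few counts. Genes that passed in the same direction in both clones numbered 4772, of which 2191 were higher and 2581 lower, and 439 of them changed at least 2-fold in both (95 higher and 344 lower). With TPM the balance of shared genes turned to 2818 higher and 1816 lower. Independent lists of the sizes called from counts would share 831.8 higher and 927.6 lower genes.

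Both comparisons use the same WT libraries, which alone makes their fold changes correlate. In 50 simulated sets of unchanged clones against shared WT libraries, the median overlap was 0 genes and the highest 1, and the median correlation of fold changes across genes was 0.504, against 0.851 observed. The simulated libraries held only the spread between libraries of a group, so their overlap was bound to be near 0. They do not cover an overlap that comes from a WT culture that differs as a whole. The observed covariance was 0.34 and the simulated 0.0169, a difference of 0.323. Among the 11517 genes at 5 CPM or more, the covariance was 0.139 against 0.00326. The 3 WT libraries cannot be split into separate control groups of more than 1 library each, so the part of the overlap that comes from shared controls was not measured directly. Genes are not independent replicates.

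**Figure D3:**
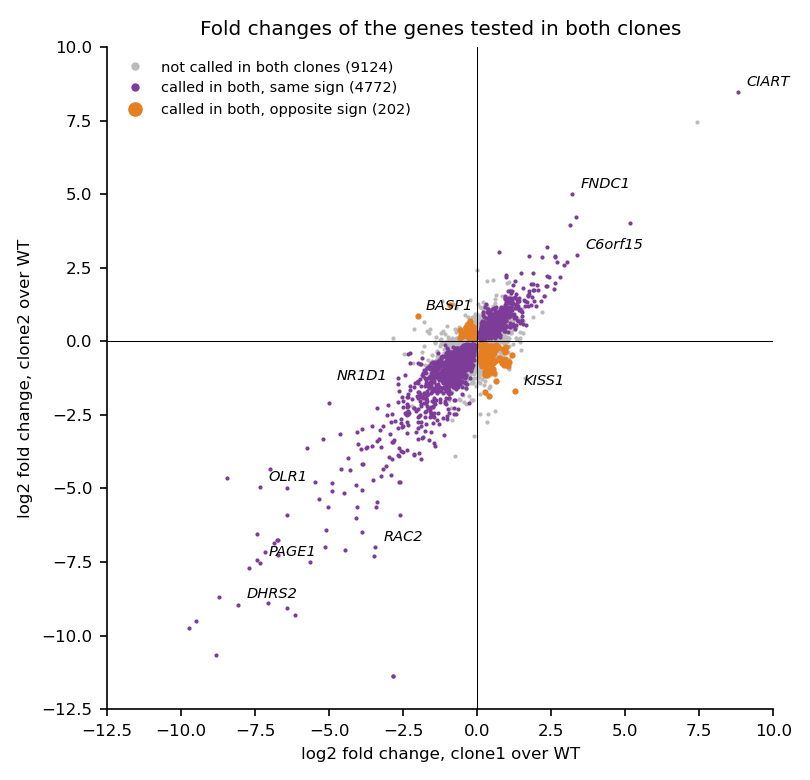
Log2 fold change of each gene tested in clone2 against WT (vertical) plotted against that in clone1 against WT (horizontal), with named genes labelled. The correlation across genes was 0.851, and 4772 genes passed in the same direction in both clones.

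The clones also differed directly from each other. Clone2 held more BASP1, a membrane-bound signalling protein (log2 fold change 2.87 ± 0.16, 10.2 ± 0.526 against 1.40 ± 0.088 CPM, SD), CXCL14 (2.44 ± 0.18), KCND3 (2.27 ± 0.10), the hormone FGF21 (1.90 ± 0.17) and FNDC1 (1.80 ± 0.13). It held less RAC2 (-3.57 ± 0.16, 0.854 against 10.2 ± 0.513 CPM), KISS1, the kisspeptin precursor (-2.96 ± 0.16), GMFG (-2.27 ± 0.18), SP140 (-2.01 ± 0.13), MARCHF4 (-1.88 ± 0.09) and SQOR (-1.81 ± 0.16). Of the clock genes, BHLHE41 (1.09 ± 0.05), DBP (0.83 ± 0.07) and NR1D1 (0.47 ± 0.09) were higher in clone2. Genes that passed numbered 4240, of which 2065 were higher in clone2 and 2175 lower, and 232 passed with at least 2-fold (56 higher and 176 lower). With TPM the split was 1176 higher and 2029 lower. The libraries of the clones did not overlap for 40.4% of the genes tested, where chance gives 10%. Of 1919 genes called in clone1 alone, 1013 differed directly between the clones, as did 1285 of 2219 called in clone2 alone. Another 202 genes passed against WT in opposite directions, 137 up in clone1 and down in clone2 and 65 the other way, and all 202 differed directly.

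Interferon-stimulated, YAP and TEAD, NF-kB and p53 genes were lower in clone2 than in clone1, in calls kept with an estimated correlation. Of 22 interferon-stimulated genes 17 were lower (18 adjusted over the list alone), including OASL (-0.83 ± 0.04), ISG15 (-0.98 ± 0.05), RSAD2 (-0.97 ± 0.06) and IFIH1 (-0.91 ± 0.06), with a median of -0.85 (adjusted p = 2.1e-14; adjusted p = 7.65e-03 with an estimated correlation). Of 14 YAP and TEAD targets 13 were lower (13 adjusted over the list alone), including CCN2 (-0.91 ± 0.04) and CCN1 (-0.69 ± 0.05), with a median of -0.42 (adjusted p = 2.31e-10; adjusted p = 0.0322 with an estimated correlation). NF-kB inflammatory genes were lower in 11 of 17 (12 adjusted over the list alone; median -0.38, adjusted p = 8.56e-06; adjusted p = 0.0224 with an estimated correlation), and p53 targets in 15 of 22 (16 lower and 1 higher adjusted over the list alone; median -0.22, adjusted p = 9.76e-06; adjusted p = 0.0224 with an estimated correlation). NRF2 targets were higher in 12 of 17 and lower in 1 (12 and 1 adjusted over the list alone), including AKR1C1 (0.93 ± 0.10) and HMOX1 (0.47 ± 0.06), with a median of 0.18 (adjusted p = 3.63e-04; adjusted p = 0.0398 with an estimated correlation).

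Further lists differed between the clones only at the preset correlation. Oxidative phosphorylation genes were higher in clone2 in 21 of 29 (22 adjusted over the list alone; median 0.18, adjusted p = 4.98e-07; adjusted p = 0.253 with an estimated correlation), G2/M genes in 15 of 24 (15 adjusted over the list alone; median 0.14, adjusted p = 2.08e-06; adjusted p = 0.102 with an estimated correlation) and S-phase genes in 13 of 24 with 1 lower (14 and 1 adjusted over the list alone; median 0.12, adjusted p = 6.24e-05; adjusted p = 0.253 with an estimated correlation). Ribosomal protein genes were higher in 14 of 32 (15 adjusted over the list alone; median 0.11, adjusted p = 4.63e-05; adjusted p = 0.497 with an estimated correlation), and fry did not pass this list (adjusted p = 0.053). Higher too were the unfolded protein response (10 of 16 higher and 1 lower, 10 and 1 adjusted over the list alone, median 0.19, adjusted p = 4.72e-04; adjusted p = 0.253 with an estimated correlation), the ATF4 list (10 of 19 higher and 3 lower, 11 and 3 adjusted over the list alone, median 0.18, adjusted p = 3.81e-03; adjusted p = 0.253 with an estimated correlation) and the E-box clock output (6 of 12 higher and 2 lower, 6 and 2 adjusted over the list alone, median 0.20, adjusted p = 8.34e-03; adjusted p = 0.102 with an estimated correlation). Lower were adhesion and integrin genes (10 of 17 lower and 1 higher, 10 and 1 adjusted over the list alone), including ITGA3 (-0.45 ± 0.04) and CD44 (-0.61 ± 0.04), with a median of -0.32 (adjusted p = 1.83e-05; adjusted p = 0.216 with an estimated correlation). The replication-dependent histones were lower in 5 of 9 (5 adjusted over the list alone; median -0.23, adjusted p = 0.0312; adjusted p = 0.216 with an estimated correlation) and the MAPK list in 8 of 18 with 2 higher (8 and 2 adjusted over the list alone; median -0.10, adjusted p = 0.0341; adjusted p = 0.43 with an estimated correlation). The histone call ended without replicate 2 of clone1 (-0.26) or clone2 (-0.26) and with other filters on low counts, and the MAPK call without clone1 replicate 2 (-0.08) or 3 (-0.11), without clone2 replicate 1 (-0.11) and without the filter on low counts (-0.07). In all, 15 of 34 lists passed by camera, 8 up and 7 down. With an estimated correlation 5 passed, and by fry 24.

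The remaining lists passed in no comparison by camera at the preset correlation, although single members moved. Among 16 clock protein modifiers the deubiquitinase USP2 fell (-2.54 ± 0.25 and -2.91 ± 0.26 in clone1 and clone2) and TIMELESS rose (0.35 ± 0.04 and 0.28 ± 0.04). In that list 5 rose and 4 fell in clone1, 4 and 6 in clone2 (list adjusted p = 0.846 and 0.707). Glucocorticoid receptor targets held falls of GLUL (-1.39 ± 0.06 and -1.20 ± 0.06) and ANGPTL4 (-3.30 ± 0.19 and -3.02 ± 0.18). Of these 17, 2 rose and 9 fell in clone1, 5 and 7 in clone2 (adjusted p = 0.085 and 0.356). With the median of neighbouring genes removed this list passed in clone1 (median -0.24, adjusted p = 0.0281). Of 9 Wnt targets 3 rose and 4 fell in clone1, 2 and 3 in clone2, with a fall of NOTUM (-1.53 ± 0.08 and -1.15 ± 0.08; list adjusted p = 0.576 and 0.716). Of 8 Notch targets 3 rose and 4 fell in each clone, with a rise of NOTCH3 (0.35 ± 0.05 and 0.70 ± 0.05; list adjusted p = 0.665 and 0.772). Of 16 TGF-beta targets 7 rose and 7 fell in clone1, 7 and 4 in clone2, with a rise of PMEPA1 (0.78 ± 0.04 and 0.83 ± 0.04; list adjusted p = 0.519 and 0.716). MMP2 rose (0.98 ± 0.04 and 1.06 ± 0.04) among 13 mesenchymal genes, of which 7 rose and 2 fell in clone1, 5 and 3 in clone2 (adjusted p = 0.0688 and 0.707). ALDOC fell (-2.50 ± 0.14 and -2.89 ± 0.15) among 23 hypoxia and glycolysis genes, of which 6 rose and 8 fell in clone1, 8 and 7 in clone2 (adjusted p = 0.518 and 0.831). EHMT2 rose (0.36 ± 0.05 and 0.50 ± 0.05) among 16 chromatin silencing genes, of which 4 rose and 5 fell in clone1, 6 and 3 in clone2 (adjusted p = 0.828 and 0.379). HLA-C rose (0.27 ± 0.04 and 0.32 ± 0.04) among 12 class I antigen presentation genes, of which 6 rose and 2 fell in clone1, 3 and 1 in clone2 (adjusted p = 0.345 and 0.716). By fry, which does not compare a list with other genes, the glucocorticoid, Wnt, Notch, TGF-beta and mesenchymal lists passed in both clones, antigen presentation in clone1, and the modifier and chromatin lists in clone2. Between the clones fry passed the ROR-element (adjusted p = 3.08e-03, down), modifier, glucocorticoid, TGF-beta, mesenchymal and chromatin lists.

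Of the marker lists for other cell types, only the chondrocyte and osteoblast lists passed camera at the preset correlation, while fry also passed the epithelial and neural lists in both clones. KRT8 fell (-0.48 ± 0.04 and -0.56 ± 0.04) among 11 epithelial markers, of which 2 rose and 7 fell in clone1, 3 and 7 in clone2 (adjusted p = 0.202 and 0.198). Nestin NES rose (0.98 ± 0.04 and 0.95 ± 0.04) among 9 neural markers, of which 4 rose and 3 fell in each clone (adjusted p = 0.202 and 0.256). TAGLN rose (1.37 ± 0.06 and 1.21 ± 0.06) among 6 muscle markers, of which 1 rose and 2 fell in clone1, 2 and 2 in clone2 (adjusted p = 0.665 and 0.883). In clone2 against clone1 the adjusted p of the ROR-element, modifier, glucocorticoid, Wnt, Notch, TGF-beta, mesenchymal, hypoxia, chromatin, antigen presentation, epithelial, neural and muscle lists lay between 0.138 and 0.912. Leukocyte, endothelial and adipocyte markers had 4 tested genes each, too few for the list test. Of these 1 leukocyte gene rose and 2 fell in clone1 and 1 fell in clone2. In clone2 2 endothelial genes rose, and 1 adipocyte gene rose and 3 fell in clone1, with 1 each way in clone2. The table holds 0 of 13 mitochondrially encoded genes, so their level was not measured.

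Some lists were called by camera in only part of the comparisons and did not pass it in the others. In clone1 these were S-phase genes (TYMS fell by 1.80 on the log2 scale; adjusted p = 0.345), YAP and TEAD targets (CCN2 rose by 0.89; 0.518), MAPK genes (FOSL1 fell by 0.61; 0.357), oxidative phosphorylation (COX5B fell by 0.27; 0.357), heat shock genes (0.357) and histones (0.659). In clone2 these were NRF2 targets (TXNRD1 fell by 0.49; adjusted p = 0.724), adhesion genes (ITGB3 rose by 1.22 and CD44 fell by 0.30; 0.999), the unfolded protein response (0.433), osteoblast markers (RUNX2 rose by 0.54; 0.305) and histones (H1-2 fell by 0.70; 0.115, or 0.0386 with the median of neighbouring genes removed). Between the clones these were collagen and matrix genes (THBS1 lower by 0.45; adjusted p = 0.186), osteoblast (0.128) and chondrocyte markers (0.666), cholesterol (0.275) and fatty acid synthesis (0.215) and heat shock genes (HSPB1 higher by 0.38; 0.11). Of these, fry passed YAP and TEAD and MAPK in clone1, NRF2, unfolded protein response, osteoblast and histones in clone2, and osteoblast, chondrocyte, fatty acid and heat shock lists between the clones. The mean lay below zero while median and test were up for clock modifiers (-0.15) and S-phase genes (-0.01) in clone1 and for hypoxia genes (-0.12) and muscle markers (-0.46) in clone2. For TGF-beta targets in clone2 the median was -0.04 and the mean -0.03 while the test was up. For adhesion genes in clone2 the mean was 0.02 and the test down. Between the clones the matrix list had a median of -0.15, a mean of 0.14 and a test of down, chondrocyte markers a median of -0.10, a mean of 0.18 and a test of up, and epithelial markers a mean of 0.04 and a test of down.

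Neighbouring genes moved together in stretches of several chromosomes. On chromosome 1 from 21596221 to 32198285 the median of expressed genes held out from the search was -0.59 in clone1 and -0.58 in clone2, on chromosome 10 from 86755763 to 125823258 it was -0.47 and -0.53, and on chromosome 21 from 37073254 to 46583871 it was -0.54 in both. On chromosome 18 from 27932879 to 80140346 it was 0.52 and 0.51. There were 10 such runs, 8 lower and 2 higher, with 610 of 11500 expressed genes. Of the 610 genes in runs, 518 (84.92%) passed in the same direction in both clones, against 33.13% of the other expressed genes. The 610 include the genes used to find the runs, so the search itself fixes part of this contrast. Of the 300 genes held out, 272 had the sign of their run in both clones, whether or not they passed. Of the 439 genes changed at least 2-fold in both clones, 19 were among the 610 genes in runs. The 439 were drawn from all genes tested, while genes below a mean of 5 CPM were not assigned to runs. With the running median of neighbouring genes removed, 3264 of the 4772 shared genes still passed in the same direction in both clones. In all 4054 genes were shared then, so the removal also added calls. It shifts genes outside the runs too, so the calls lost are not a count of genes moved by runs.

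**Figure D4:**
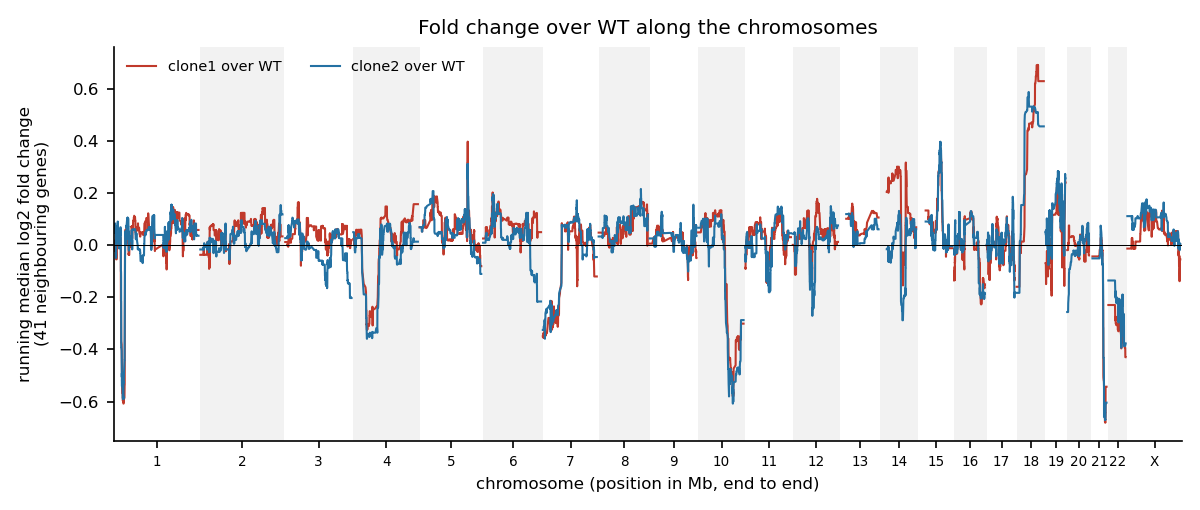
Running median log2 fold change of expressed genes along the chromosomes in clone1 and clone2 against WT. Both clones run below zero on chromosome 1 from 21596221 to 32198285 (held-out medians -0.59 and -0.58) and above zero on chromosome 18 from 27932879 to 80140346 (0.52 and 0.51).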

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

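Among the tests in this part, those of the CIART level and the removal of the running median of neighbouring genes were chosen after the result was seen.

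Clone2 and clone1 differed directly in 4240 genes and 15 lists, and each value here is a tested difference of clone2 minus clone1 on the log2 scale. The interferon-stimulated list had a median of -0.85, YAP and TEAD targets -0.42, NF-kB inflammatory genes -0.38, adhesion genes -0.32, histones -0.23, p53 targets -0.22 and MAPK genes -0.10. The E-box clock output had a median of 0.20, the unfolded protein response 0.19, ATF4 genes 0.18, NRF2 targets 0.18, oxidative phosphorylation 0.18, G2/M genes 0.14, S-phase genes 0.12 and ribosomal proteins 0.11. With an estimated correlation 5 of the 15 list calls passed: the interferon-stimulated, YAP and TEAD, NF-kB, p53 and NRF2 lists (adjusted p = 7.65e-03 to 0.0398), while the others did not (adjusted p = 0.102 to 0.497). Higher in clone2 were BASP1 (2.87), CXCL14 (2.44), OLR1 (2.36), KCND3 (2.27), FGF21 (1.90), FNDC1 (1.80), HTR2A (1.15), LEFTY1 (0.90) and NWD1 (0.86). Lower were RAC2 (-3.57), KISS1 (-2.96), GMFG (-2.27), SP140 (-2.01), MARCHF4 (-1.88), SQOR (-1.81), DHRS2 (-0.87), HAPLN2 (-0.80), KCNH1 (-0.65), C6orf15 (-0.45), CNTN1 (-0.44), CIART (-0.35), MMP9 (-0.34) and LCTL (-0.31).

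Of the clock genes, BHLHE41 (1.09), DBP (0.83), NR1D1 (0.47), PER3 (0.29), PER1 (0.21) and TEF (0.20) were higher in clone2, and RORA (-0.27), NPAS2 (-0.26), PER2 (-0.23) and BHLHE40 (-0.16) lower. The PER2 call ended without clone1 replicate 1 or 3 or clone2 replicate 1 or 3 (-0.22 to -0.17), the TEF call without clone1 replicate 1 or clone2 replicate 1 or 2 (0.17 to 0.19), the BHLHE40 call without clone1 replicate 3 or clone2 replicate 1 or 3 (-0.13 to -0.12) and the RORA call without clone1 replicate 3 (-0.19). With the running median of neighbouring genes removed the calls of PER1 (0.11) and TEF (0.082) ended, with TPM those of PER3 (0.22), TEF (0.14) and PER2 (-0.22), and with DESeq2 those of TEF (0.20) and PER2 (-0.22).

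Of 22 interferon-stimulated genes 9 passed above WT in clone1 and below it in clone2, among them ISG15 (0.28 and -0.70), OASL (0.66 and -0.16), IFIT3 (0.31 and -0.90) and DDX58 (0.56 and -0.38), while BST2 fell in both (-3.25 and -3.59). Neither list call against WT passed with an estimated correlation (adjusted p = 0.116 and 0.0815). A graded response to the higher CIART level of clone1 alone would keep each gene on 1 side of WT, yet 40.9% of the listed genes passed in opposite directions. With 1 clone at each CIART level, such a response joined to an effect of picking a clone is not excluded. With the running median of neighbouring genes removed 8 of the 9 genes still did; the clone2 call of IFIT1, in the lower run on chromosome 10 with IFIT3, ended (-0.63 before, -0.11 after). GC content or gene length left the list median at -0.85 after their trend was removed. The list means of the libraries lay at 4.54 to 4.62 log2 CPM in clone1, 4.39 to 4.49 in WT and 3.85 to 3.90 in clone2. The gap of 0.484 between WT and clone2 argues against a single library there. The gap of 0.0488 between clone1 and WT is smaller than the spread of the WT libraries and does not settle this for clone1. The difference between the clones may be biological, as a hypothesis. No other biological explanation was tested.

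Over all genes called in both clones, 4.06% passed in opposite directions. For these genes as a set a response to the CIART level that turns at some dose, GC content or gene length, and dosage of neighbouring genes cannot be told apart, because 2 clones give 2 CIART levels and each correction left only part of the set: 137 genes passed in opposite directions after the GC and length trend was removed and 112 after the running median of neighbouring genes was removed.

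For the comparison of clone2 with clone1 the 10 splits of the 6 libraries are too few for a share under 0.05; the real split alone (1 of 10) gave 4240 genes and the highest other 0 by edgeR, with 1165 at an unadjusted p under 0.05 against 5532, and for lists the real split (1 of 10) gave 15 and the highest other 11.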

How the results depend on the processing

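The removal of the running median of neighbouring genes was chosen after the data were seen. Of 459 named-gene calls, 397 kept direction and side of the threshold under every alternative run, as did 8 of 44 list calls; over 7208 alternative values of named genes 7046 did, 127 lost the call, 12 changed sign and lost it, and 23 gained it.

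Leaving out each library gave 8.80 to 8.84 for CIART in clone1 and 8.44 to 8.49 in clone2, 6003 to 6707 genes in clone1, 6456 to 6920 in clone2, 3313 to 4206 between the clones and 4165 to 4763 shared, and 13 to 14, 14 to 15 and 14 to 15 lists. An adjusted p under 0.01 left 2765 genes between the clones, and a change of at least 2-fold left 669, 759 and 232 genes in the 3 comparisons and 439 shared; both thresholds are stricter by construction. An estimated correlation passed 0, 3 and 5 lists and fry, which asks another question, 26, 29 and 24; the cause was not tested. DESeq2 called 5778, 6243 and 3293 genes with 4001 shared, and TPM with 1 added 6898, 6715 and 3205 with 4634 shared; with TPM 65.8%, 56.95% and 36.7% of these were higher, and 60.8% of the shared, against 49.3%, 47.95%, 48.7% and 45.9% from counts.

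With the running median removed 12 named results changed sign and no longer passed: in clone1 TEF (0.13), CLOCK (0.10), BTRC (0.13), BMP4 (-0.052), BAG3 (0.089), ATP5F1A (-0.034) and HDAC1 (0.048); in clone2 CLOCK (0.017), RORA (-0.044) and XBP1 (0.058); between the clones NFKBIA (0.0044) and PCNA (0.021). The construction shows the cause: the median of their neighbours exceeded their own change.

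A replicate block called 6628, 6956 and 3925 genes with 4575 shared and 14, 15 and 15 lists. Libraries of the same number in different groups correlated by -0.147 to 0.104, and 2 of 9 libraries correlated best with their own number, so the numbers carry no visible pairing. With it 4 named calls ended: GAGE12E and GAGE12C in clone2, PER1 in clone1 (-0.12) and MSMO1 between the clones (-0.18). At this depth, genes below the count filter were not tested.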

Other observations

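Among the tests in this part, those of loss of a segment, of copy number in the runs on chromosomes 15 and 21, of cells that differ within the WT culture and of paralogs for the genes with less sequence of their own were chosen after the result was seen, as were the gene families below.

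Most genes of the protocadherin beta cluster, which encodes cell-surface adhesion proteins, rose in both clones. Of 15 beta genes tested 13 rose in clone1 and 15 in clone2, with medians of 1.11 and 1.41, among them PCDHB6 (2.69 and 2.70), PCDHB13 (1.37 and 1.41), PCDHB5 (0.71 and 0.83) and PCDHB2 (0.68 and 0.60). Of 20 gamma genes 8 rose and 3 fell in clone1 and 9 rose and 1 fell in clone2 (medians 0.62 and 0.69), and of 15 alpha genes 6 and 7 rose (medians 0.43 and 0.68). Of 16 CC and CXC chemokines 5 rose and 7 fell in clone1 and 4 rose and 11 fell in clone2, with medians of 0.11 and -0.92. CXCL10 (0.90 and -0.66), CXCL11 (1.07 and -0.69) and CCL5 (0.34 and -1.15) rose in clone1 and fell in clone2.

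Runs of neighbouring genes that moved together in both clones lay on chromosomes 1, 4, 7, 10, 15, 18, 21 and 22. In 0 of 1000 random orders of the genes did runs hold as many genes, which argues against a chance order of genes. GC content or gene length left 98.9% of the median shift, taken over all runs and both clones. The 2 runs on chromosome 22 lost more in clone1. There the held-out medians went from -0.37 to -0.26 and from -0.43 to -0.31. In clone2 they went from -0.28 to -0.26 and from -0.29 to -0.26. Of genes held out from the search, 90.67% had the sign of their run in both clones. This is above the 75% set for a chromosome copy number that differs between the cultures. Any cause that shifts neighbouring genes together would give the same, so the test does not single out copy number. The share was 73.3% in the run on chromosome 15 and 69.6% in the run on chromosome 21, below the 75% set for this test. For these and the other runs, copy number cannot be told apart from other causes of a regional shift. No DNA was measured.

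Genes measured in WT at 5 CPM or more and below 0.5 CPM in both clones numbered 13, of 14 in clone1 and 19 in clone2, where independent lists share 0.02: PAGE1, GAGE1, VCX, PNMA5, MAGEA2, MAGEA2B, ETV1, MLPH, VCX3A, OR51B5, SPATA31C2, PXMP4 and PAGE5. Of these 61.5% lie on the X chromosome, against 3.87% of the expressed genes. Loss of a segment would lower the neighbouring genes, whose median was 0.0285 over the 13. Their median fall was at most 4.76% of the fall of the gene itself on the log2 scale, the highest being that of ETV1. This argues against a loss of all copies of a segment that spans the neighbours. It cannot exclude loss of 1 of several copies, which lowers the neighbours far less than a full loss. For ETV1 such a loss stays open, since the median of its neighbours was -0.34 in clone1 and -0.31 in clone2. A loss too small to reach the neighbours was not tested. Of the genes, 7 have at least 80% of the 31-base words of their longest transcript in no other gene. This argues against reads shared between paralogs for them, except for GAGE1. GAGE1 has 85.7% such words but shares others with GAGE12 genes, and where its reads fell was not measured. For the other 6 this cannot be told apart from a change of the gene, since 20.4% or less of such words are their own, or 72.3% for PAGE5. Cells that differ in these genes within the WT culture may account for the loss, and 0 genes gained in both clones leave this open, since a gain needs cells that are rare in WT. Silencing of the genes in both clones stays open and was not tested.

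For clone1 against WT and for clone2 against WT the 10 splits of 6 libraries are too few for a share under 0.05. The real split (1 of 10) gave 6893 genes in clone1 and 7193 in clone2 against 0 as the highest other by edgeR, with 859 and 657 at an unadjusted p under 0.05 against 7712 and 7927. For lists the real split (1 of 10) gave 14 and 15 against 7 and 11. For genes changed the same way in both clones, 1 of 100 partitions drawn of the 9 libraries, the real one with 4772, gave as many. Partitions that mix the groups widen the spread within a group. The count therefore shows only that libraries of the same label are alike, not why the clones share changes. In 0 of the partitions drawn were the groups kept whole with a clone in the place of WT. The highest other, 3712, kept the WT libraries together and mixed those of the clones, and the next gave 553.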
